A study of Homo sapiens with 6 samples.

How the data were processed

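H9 cells with a PAX6-tdTomato reporter and inducible Cas9 were transduced with guide library A or B at a multiplicity of infection of 0.3, selected with puromycin, given doxycycline for 5 days and sorted for tdTomato, per the labels' protocols. Guide sequences were amplified from genomic DNA by PCR and sequenced. Genomic coordinates and guide sequences were not used here. Submitters' processing notes name cutadapt 1.11, Bowtie2 2.3.4.3 and MAGeCK, with no parameters, and the index, genome build and normalization method are not given in the sources used here.

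The files are named as raw counts, but the deposited values are normalized signal, read counts multiplied by a scaling factor, since they are not whole numbers. In the pool columns 100% of values were whole multiples of a single step (1.87 units in A and 1.42 in B, within 0.01 of a whole number), so reads were recovered by dividing by it. The ko column of each library is a single deposited signal for its 2 ko samples, and how the authors combined them is not given in the sources used here. Low ko values (up to 300 units) fell on 2 series of whole-read steps, fitted as smooth curves from start values read off the low values. Within 0.005 units, 94.2% of these values in A and 94.0% in B lay on a series, against 0.0495% and 4.06% on the same series moved by 0.5 of a step. In A, 91.4% lay on the first series and 2.77% on the second alone, and in B 30.7% and 63.3%. A first set of coarser start values placed 94.0% in A but 44.6% in B, and it was replaced after that result was seen because some start values had been matched to file values off the series.

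The tests planned before the data were examined assumed raw counts of 6 libraries. Count models per guide, the agreement of the 2 ko samples and the omission of a ko sample in turn could not be run on a combined column. In their place each guide was scored as log2((ko CPM + 2) / (pool CPM + 2)), with CPM from column totals and at least 10 pool reads, and guides at least 4-fold higher were counted without a test. Such a ratio understates changes of guides at low levels. The CPM of a ko column is a share of combined units, not of known reads. A count of 0 in a pool library allows up to 3 reads (0.173 CPM in A and 0.189 in B).

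Genes with at least 2 guides were tested by robust rank aggregation (alpha 0.25) on percentile ranks within each library, absent guides sharing the last rank. Null values came from 1e+06 random draws of guides' own percentiles, in place of the uniform ranks first planned, because of the tied absent guides. The test is one-sided for enrichment. Benjamini-Hochberg adjustment was used throughout at 0.05. Gene lists fixed before the data were examined were compared by the median of gene scores with 100000 random lists of the same size, drawn with replacement, on both sides. Classes of guides were compared by 100000 random relabellings of guides, on both sides. The kept share adjusted for pool reads, which subtracts the share among gene-targeting guides of the same library in 40 bins of pool reads, was added after the data were examined. Summed CPM per gene was tested with limma 3.58.1 in R 4.3.3 on 4 columns with library and arm as terms and columns centred on their median, which left 1 residual degree of freedom and a prior of 18.3. The limma p rests on how far the A and B ratios of a gene disagree, pooled in part with that of all genes. The remaining p-values measure the spread between guides or genes of these libraries. None measures spread between cultures, since nothing in the labels describes separate cultures.

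Names were matched to a table of human genes, 17373 by symbol and 1352 by synonym, and 190 were kept as in the files. The text names PAX6, the 12 genes with the smallest rank aggregation p, 2 members per list, per library 4 guides highest in ratio and 2 absent guides with the most pool reads (in place of the smallest p), the 3 genes with the smallest p in the summed fit and 2 microRNA targets. GDF11 and ITIH1 were named after their values were seen. For growth brakes, 1 of the 2 members is not reported here.

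Scripts were tested on simulated screens with 199 changed genes among 18855. With nothing changed, 0 of 18855 genes passed. The summed fit recovered 0% of changed genes at 16-fold and 97.5% at 64-fold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Alternatives covered scaling, filters, pseudocounts, rank rules, single libraries and list scores.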

Results

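Guide RNA abundance was measured by amplicon sequencing of genomic DNA from H9 human embryonic stem cells that carried a tdTomato reporter at PAX6, a transcription factor gene of the early neural lineage, and a Cas9 nuclease switched on by doxycycline. The cells had received 1 of 2 lentiviral guide libraries, A and B, and were sequenced on day 17. The series has 6 samples. Each guide library had 1 pool sample and 2 ko samples, and the 2 ko samples stand in a single column of combined values, so no value below has an SD between replicates. The labels list 5 doxycycline plates and 1 control plate, alike for all samples. They do not say what separates pool from ko samples beyond these names, and the text keeps the names. Per the labels, tdTomato-positive cells were collected by sorting, which frames the question of which gene losses go with activation of the PAX6 reporter.

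The pool columns came to 17364303 reads for library A over 63950 guides and 15865800 reads for library B over 56869 guides, with medians of 203 and 219 reads per guide. Library A held 56116 guides against 18873 genes, 6834 guides against 1795 microRNA targets and 1000 non-targeting guides. Library B held 55869 guides against 18834 genes and 1000 non-targeting guides. The read depth of the ko columns is unknown, because their values were normalized and combined, and their totals were 34845053 units in A and 33567975 units in B.

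Guides were missing from the ko columns more often than from the pool columns, and far more so in library B. A value above 0 was held by 48.2% of guides in the A ko column (Wilson 95% interval 47.8% to 48.6%) and by 8.23% in the B ko column (8.01% to 8.46%), against 94.1% and 97.2% in the pool columns. Among guides with at least 10 pool reads, 52.2% of 58860 in A and 8.59% of 54319 in B held a ko value above 0. The ko counts were also concentrated in few guides. The first 88 guides held 50% of the B ko total, where 12280 guides were needed in the B pool, and 1959 guides held 50% of the A ko total against 12682 in the A pool. Guides with more pool reads were kept more often: among gene-targeting guides the kept share went from 12.8% in the lowest decile of pool reads to 89.9% in the highest in A, and from 2.12% to 19.7% in B. Intervals treat guides as independent draws and cover no spread between samples or cultures. PCR reads are not independent molecules either.

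**Figure D1:**
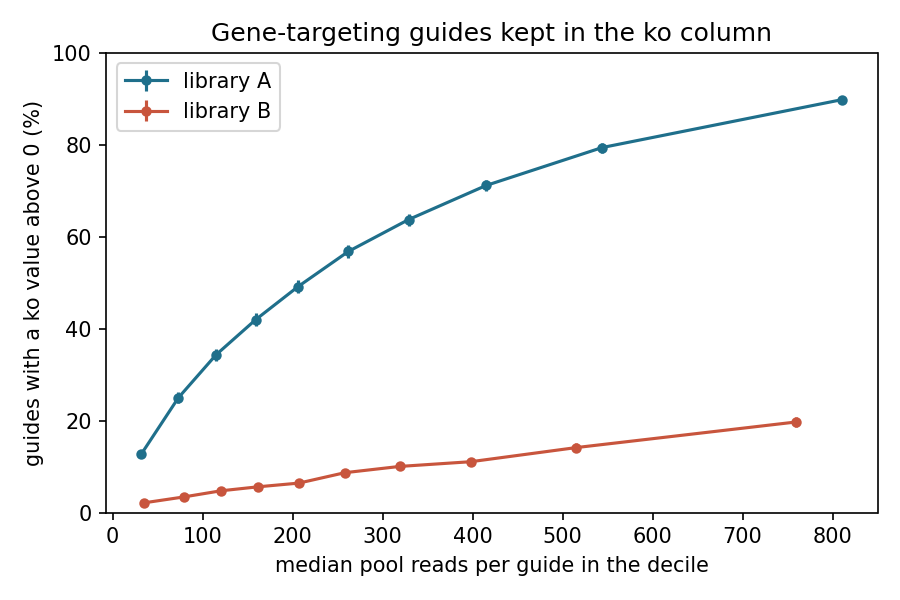
Share of gene-targeting guides with a ko value above 0 (y axis, percent) against the median pool reads of each decile of guides (x axis), with Wilson 95% intervals as bars. In library A the share runs from 12.8% to 89.9%, and in library B from 2.12% to 19.7%.

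In library A the guides furthest above their pool level targeted GTF2H4, a subunit of the general transcription and repair factor TFIIH, PCDHAC2, a protocadherin, IDI1, an isomerase of isoprenoid synthesis, and SAE1, a subunit of the SUMO-activating enzyme. Their log2 ratios of ko over pool, on the scale of CPM plus 2, were 9.27, 8.46, 8.39 and 7.63. The GTF2H4 guide alone held 0.636% of the A ko total. Of 58860 guides with at least 10 pool reads, 2691 (4.57%) stood at least 4-fold higher, and these held 50.1% of the ko total. The share was 4.49% of gene-targeting guides (4.32% to 4.67%), 4.70% of microRNA guides (4.19% to 5.26%) and 8.36% of non-targeting guides (6.72% to 10.4%). Among guides absent from the ko column, those with the most pool reads targeted SYNE4, with 1702 pool reads, and KIF13A, with 1597. Scaling to the non-targeting guides lowered the count of higher guides from 2691 to 1323. With a single combined ko column these differences have no replicate check.

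In library B the guides furthest above their pool level targeted TMC8, USF1, a basic helix-loop-helix transcription factor, GRIN2D, a subunit of the NMDA receptor, and UPRT. Their log2 ratios were 10.29, 10.23, 9.91 and 9.85, and the TMC8 guide held 2.68% of the B ko total. Of 54319 guides, 1225 (2.26%) stood at least 4-fold higher, and these held 89.5% of the ko total. The share was 2.24% of gene-targeting guides (2.12% to 2.37%) and 2.87% of non-targeting guides (1.98% to 4.14%). Among absent guides, those with the most pool reads targeted APOBEC3H, with 2729 pool reads, and KIF13B, with 2321. These differences have no replicate check either.

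Guides against PAX6 itself, the reporter locus, were not found above their pool level. In A, 2 of 3 PAX6 guides were present, with log2 ratios of -2.91 and -3.16, and in B 0 of 3 were present. Over all gene-targeting guides the kept shares were 52.4% in A and 8.58% in B, and the median log2 ratio in A, absent guides included, was -1.77.

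No gene was called enriched over both libraries. The genes ranked first by rank aggregation of their guides were CLVS2, SSNA1, PCDHAC2, LUM, UBE2G2, ELTD1, GTF2H4, BTLA, TMC8, FAM227A, FBXL2 and MEOX1, and all 12 had an adjusted p of 0.792. CLVS2 had 3 of 3 A guides and 2 of 3 B guides present, with a mean log2 ratio of 0.76 and a rank aggregation p of 8.9e-05. Mean ratios of genes include absent guides, whose ratio follows their pool reads. SSNA1 had 2 guides present in each library and a mean log2 ratio of 0.93. LUM, which encodes the matrix proteoglycan lumican, had 3 A guides and 1 B guide present (mean log2 ratio 0.45), and UBE2G2, a ubiquitin-conjugating enzyme, had 3 present in each (0.81). A guide counts as present at any ko value above 0, also below its pool level. Examples are a CLVS2 guide in A (log2 ratio -2.35), an SSNA1 guide in B (-4.32) and a UBE2G2 guide in A (-2.54). Guides with a percentile rank within the alpha of 0.25 numbered 4 for CLVS2, 3 for SSNA1, 4 for LUM and 5 for UBE2G2. For GTF2H4 the rank rested on the single A guide, since its remaining A guides were absent and the only B guide present had a log2 ratio of -3.43. For PCDHAC2 the rank rested on 1 A guide, with its only B guide absent, and for TMC8 on 1 B guide. With the strongest guide left out, the rank aggregation p of GTF2H4 and TMC8 was 1.

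Over 18855 genes, 0 passed a false discovery rate of 0.05, and 946 had an unadjusted p under 0.05 where chance gives 942.75. Library A alone gave 0 of 18370 genes and library B alone 0 of 18517. These p-values treat guides as units, so they compare these libraries and not cultures. In simulated screens with the kept shares of both libraries, the same test recovered 0% of 199 changed genes at a 4-fold effect of all guides, 72.9% at 16-fold and 98.5% at 64-fold.

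**Figure D2:**
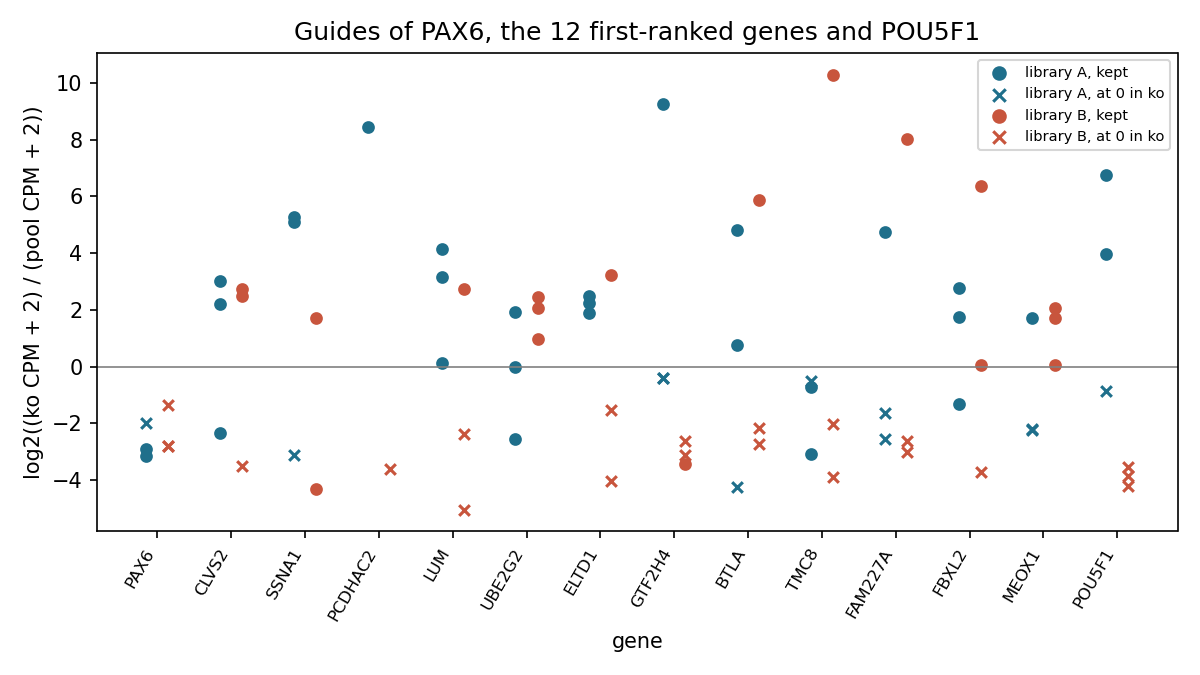
Log2 ratio of ko over pool, in CPM plus 2 (y axis), for each guide of PAX6, the 12 genes ranked first and POU5F1 (x axis), with circles for guides kept in the ko column and crosses for guides at 0 there, whose position is set by their pool level. Single guides reach 9.27 for GTF2H4 in A and 10.29 for TMC8 in B, next to absent guides of the same genes.

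Depleted genes could not be ranked, because absent guides share a single rank and made up more of each library than the test takes into account. All guides were absent for 2105 genes. Shuffling guides within each library gave 2120 ± 34.1 such genes (SD over 1000 shuffles, permutation p = 0.677). The 8 depleted genes planned for naming are therefore not named.

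Genes that ranked high in library A did not rank high in library B more often than chance. Of 18109 genes tested in both, 949 had a p under 0.05 in A and 915 in B, and 46 had both, where independent lists give 47.95 (odds ratio 0.955, Fisher's exact test p = 0.820). Kept shares adjusted for pool reads correlated weakly between A and B, with a Spearman coefficient of 0.0163 across 18764 genes (permutation p = 0.0250). At a threshold of 0.01 the genes in both were GDF11, a TGF-beta family ligand, and ITIH1, against 2.19 given by chance. At least 2 guides 4-fold higher were found for 269 genes, against 249 ± 13.3 after shuffling guides (permutation p = 0.148).

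The fit on CPM summed over each gene's guides placed FAM227A, LRRC61 and RMND5A first. FAM227A had a log2 ratio of 8.31 (SE 1.54) relative to the median gene, LRRC61 6.98 (SE 1.40) and RMND5A 6.70 (SE 1.35). FAM227A and LRRC61 had 1 of 3 guides present in each library, so their sums rest on single guides, and RMND5A had 2 of 3 present in A and 1 of 3 in B. The limma adjusted p was 0.388 for each, and 0 of 18764 genes passed 0.05, with 1086 at an unadjusted p under 0.05, all of them higher in ko. Scaled to library totals without centring, 4790 had an unadjusted p under 0.05 and 19 of these were higher, so count and direction depend on the scaling. Before centring, the median gene stood at -1.30 in A and -4.65 in B, and ratios are relative to those shifts.

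Among pluripotency factors POU5F1, the OCT4 gene, stood first of the 16 measured members. Its A guides had log2 ratios of 6.76 and 3.98 with the third absent, and 0 of 3 guides were present in B. Its rank aggregation p was 0.00194 over both libraries, with an adjusted p of 0.933 over all genes and 0.0310 adjusted over the list alone, so 1 member passed over the list alone and 0 over all genes. Adjustment over a list alone ran within each of 27 lists and not across them, so some such calls are given by chance. The call over the list alone was lost with the strongest guide of each gene left out (adjusted rank aggregation p 0.0746) and in library B alone (adjusted p 1), where its guides were all absent. DPPA4 followed with 1 guide present in each library (adjusted p 0.961). The list's median score lay at percentile 78.8 of random gene lists of its size.

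Signalling lists did not stand apart from random lists of genes. Gene scores of all lists include absent guides, whose ratio follows their pool reads, so percentiles depend in part on pool level. Median scores lay at percentile 61.4 for Activin/Nodal/TGF-beta signalling, with ACVR1B and LEFTY1 first, 17.8 for BMP signalling, with SMAD5 and SMAD9 first, and 69.2 for FGF/ERK signalling, with MAPK3 and GRB2 first. WNT signalling lay at percentile 89.9, where GSK3A, a kinase that restrains beta-catenin, had 5 of 6 guides present, with log2 ratios from -3.19 in B to 2.92 in A. CSNK1A1 followed with 3 A guides (from -3.81 to 2.75) and 0 B guides present. The Hippo pathway, with STK4 and WWTR1 first, lay at 60.6, Notch signalling, with RBPJ and DLL4, at 4.67, Hedgehog signalling, with SMO and PTCH1, at 15.8, and the retinoic acid pathway, with STRA6 and DHRS3, at 6.66. In these lists 0 members passed adjusted over the list alone.

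Chromatin lists gave percentiles of 83.8 for Polycomb complexes, with MTF2 and RING1 first, 97.7 for SWI/SNF complexes, with ARID1B and SMARCC1, and 83.3 for NuRD, CoREST and SIN3 complexes, with MTA3 and MBD2. DNA methylation and H3K9 methylation genes, with CBX3 and DNMT3L first, lay at 70.9 and COMPASS H3K4 methyltransferases, with RBBP5 and MEN1, at 10.3. The SWI/SNF list had an unadjusted permutation p of 0.0470 and an adjusted p of 0.630. A single MTA3 guide in B had a log2 ratio of 8.28, and 0 members of these lists passed adjusted over the list alone.

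Lists of genes with general functions in dividing cells did not pass in the planned test. Ribosomal proteins lay at percentile 1.06 (unadjusted permutation p = 0.0212, adjusted 0.573), and lower than random lists with an adjusted p of 0.00378 when gene scores were the median over guides. Such a median can fall on absent guides, whose ratio follows their pool reads. The kept share of ribosomal proteins over both libraries, adjusted for pool reads, shifted by -2.46 points (permutation p = 0.161). In the planned score, random lists matched on pool reads gave an adjusted permutation p of 0.237. The proteasome lay at 40.1, the spliceosome core at 49.2, DNA replication at 23.9, mitochondrial complex I at 37.6 and neddylation and cullin ligases at 77.4. First in these lists stood RPS29 and RPL38, PSMD3 and PSMA6, SF3A1 and SNRPB, RPA2 and GINS1, NDUFA10 and NDUFB3, and CAND1 and COPS8. SF3A1, a splicing factor, had an adjusted p of 0.0432 over the list alone, resting on 1 A guide at a log2 ratio of 7.42 with its 2 remaining A guides at -2.57 and -3.65. With the strongest guide left out its adjusted p over the list alone was 1.

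Of the remaining lists, p53 pathway activators lay at percentile 67.1, with BAX, a pore-forming cell death protein, first with 4 of 6 guides present, and BBC3 next. Growth brakes, with CSK among the first members, lay at 26.95, miRNA biogenesis, with DDX17 and DICER1, at 32.1, and neural induction factors, with POU3F2 and NR2F1, at 10.8. Mesendoderm and trophectoderm factors, with MIXL1 and MSX2, lay at 89.4, genes of dissociation-induced death and contractility, with ROCK2 and ABR, at 85.3, and olfactory, taste and hair keratin-associated genes, with OR5K3 and OR13G1, at 95.5. In these lists 0 members passed adjusted over the list alone. Of 27 gene lists, 0 passed an adjusted p of 0.05 and 2 had an unadjusted p under 0.05. Against random lists matched on pool reads, an added alternative, 0 of 27 passed as well. Some percentiles moved there, such as BMP signalling to 33.1 and DNA replication to 7.76, while pluripotency factors lay at 77.6. In library A alone 1 list, the olfactory group, passed, with an adjusted p of 0.00324.

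Non-targeting guides were kept more often than gene-targeting guides in library A. The kept share was 61.2% (58.0% to 64.3%) of 897 non-targeting guides, 56.8% (54.1% to 59.4%) of 1344 guides against olfactory, taste and hair keratin-associated genes, 52.4% (51.9% to 52.8%) of 51919 gene-targeting guides and 49.7% (48.4% to 50.9%) of microRNA guides. The median log2 ratio of non-targeting guides was higher than that of gene-targeting guides by 0.73 (permutation p = 1e-05, the smallest that 100000 relabellings can give). In library B the kept shares were 9.24% (7.55% to 11.3%) and 8.58% (8.35% to 8.82%), and the medians differed by 0.24 (permutation p = 2e-05). Medians in both libraries include absent guides, whose ratio follows their pool reads, and in B nearly all guides were absent. Adjusted for pool reads, the kept share of non-targeting guides was higher by 13.3 points in A (SE 1.48, permutation p = 1e-05) and by 1.55 points in B (SE 0.927, permutation p = 0.0880). MicroRNA guides in A had fewer pool reads than gene-targeting guides (median 174 against 232). Adjusted for pool reads their kept share was higher than that of gene-targeting guides, by 3.39 points (SE 0.607, permutation p = 1e-05), the reverse of the raw shares.

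**Figure D3:**
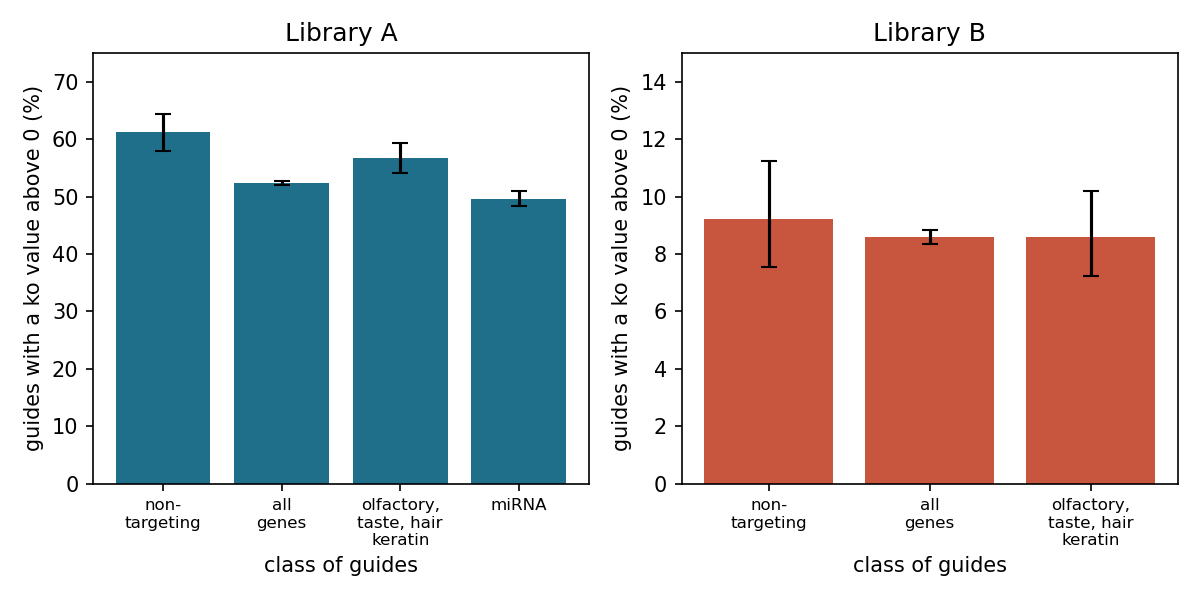
Share of guides with a ko value above 0 (y axis, percent, different ranges for the 2 libraries) by class of guides (x axis), with Wilson 95% intervals as bars. In A, 61.2% of non-targeting and 52.4% of gene-targeting guides were kept, and in B 9.24% and 8.58%.

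Among microRNA targets, present in library A only, hsa-mir-3910-1 had 4 of 4 guides present (mean log2 ratio 1.36) and hsa-mir-664a 3 of 4 (1.50). Both had an adjusted p of 0.613, and 0 of 1723 targets passed, with 90 at an unadjusted p under 0.05 where chance gives 86.15. The embryonic stem cell clusters around miR-302 and miR-371 had 45.1% of their guides present and an adjusted permutation p of 0.209 for their median score, and the miR-17 cluster with its paralogues had 56.0% and 0.209.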

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

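The tests in this part were chosen after the results were seen. Guides with 0 reads in a pool library but a value in the matching ko column stood out as signal outside the comparisons, which need at least 10 pool reads. There were 17 such guides among 3771 in A, with values up to 323.5 units, and 3 among 1614 in B, with values up to 914.7 units. Of these, 2 in A and 1 in B were non-targeting guides. No explanation was tested for them.

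Non-targeting guides were kept more often than gene-targeting guides in the A ko column. A difference in pool level is argued against as the whole cause, since the adjusted difference was 13.3 points (SE 1.48). Loss of guides against genes the cells need is also argued against as the whole cause, since non-targeting guides exceeded guides against olfactory, taste and hair keratin-associated genes by 8.51 points (SE 1.87). DNA cutting by Cas9 as such may contribute, but in B the same difference was 2.03 points (SE 1.18), and with so few guides kept there this cannot be told apart from no difference. Guide sequence and amplification stay open, as sequences were not used here.

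A few guides held most of the ko counts, and high-ranking genes were shared between A and B no more often than by chance. Too few reads are argued against, because 80.4% of the 33134 guides absent in A and 94.3% of the 52189 absent in B would stand at 10 or more of the larger read steps at their pool share. Chance spread over few founder cells, alike for all classes of guides, is argued against as the whole cause in A, where the share at least 4-fold higher was 3.81 points greater (SE 0.929) for non-targeting than for gene-targeting guides after adjustment for pool reads, while the 0.728 points (SE 0.546) in B cannot be told apart from no difference. Effects of the targeted genes are argued against as the main cause of 4-fold higher guides, since non-targeting guides have no target gene. Their share at least 4-fold higher was 8.36% (6.72% to 10.4%) against 4.49% of gene-targeting guides in A. In B it was 2.87% (1.98% to 4.14%) against 2.24%. The overlap of genes called in A and B was not used for this. The odds ratio for genes called in both was 0.955 (95% interval 0.705 to 1.29). What odds ratio such effects would give was not computed, and only 8.58% of gene-targeting guides were kept in B. In simulated screens rank aggregation recovered 0% of changed genes at a 4-fold effect of all guides and 72.9% at 16-fold. Kept shares adjusted for pool reads correlated at 0.0163 between A and B across 18764 genes (permutation p = 0.0250). Gene effects stay open, and so does chance spread beside another cause, since the number of cells sequenced is not known here.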

How the results depend on the processing

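Alternatives named here as added were chosen after the data were examined. No paired analysis was possible because the pool libraries carry no replicate number and the ko samples come as one combined column. For the same reason count models, ranking by signed p, the agreement of ko samples and omission of each ko sample were not run. Ranks of depleted genes were not run because absent guides tie, and the summed fit has no residual degrees of freedom without a column. The count of enriched genes stayed at 0 under all settings run, with the smallest adjusted p between 0.312 and 0.935. It follows that the 67 named genes kept their side of the threshold over all genes in 467 of 467 values, which is no separate check. As added alternatives, adjustment over the list alone gave POU5F1 0.0746 and SF3A1 1 with the strongest guide left out and 1 for both in library B alone, where all their guides were absent, past the threshold no longer. The rest of the settings kept these 2 calls, which were not adjusted across lists, and the cause was not tested. The joined lists of genes needed by dividing cells, kept less often in A, missed the threshold when DNA replication was left out as an added alternative (-3.67 points, permutation p = 0.116), and the cause was not tested. Guides 4-fold higher in A fell from 2691 to 1323 when non-targeting guides set the scale, and the cause was not tested. Genes high in both A and B came to 46 with a pool count of at least 30 (odds ratio 1.02) and, as an added alternative, to 48 with guides ranked by ko level (odds ratio 1.02). Both turned the direction, with neither past the threshold, and the cause was not tested. Gene lists past the threshold went from 0 to 1 with the median over guides (ribosomal proteins, adjusted p 0.00378), to 1 in library A alone and, as an added alternative, to 1 with the kept share in A (both the olfactory group), and the cause was not tested. The kept share of ribosomal proteins over both libraries, adjusted for pool reads, did not pass (adjusted permutation p = 0.782). With at least 10 reads the guides present came to 92.04% in the A pool and 95.5% in the B pool. With at least 10 units they came to 44.7% in A ko and 7.77% in B ko. All are fewer by construction, and units are not reads, so the pool and ko cutoffs differ. In the summed fit, unadjusted calls numbered 1086 centred, all higher, and 4790 with library totals only, of which 19 were higher; 416 were left with a pseudocount of 0.5 CPM, and 0 passed in each. The low kept share in B limits what single genes can show there.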

Other observations

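The tests on kept shares and on POU5F1 in this part were chosen after the results were seen. Kept shares in the A ko column were compared with random gene lists for lists of genes needed by dividing cells. Adjusted for pool reads, the shift was -3.38 points for ribosomal proteins (unadjusted permutation p = 0.274), -8.52 for the proteasome (0.0814) and 1.23 for the spliceosome core (0.833). It was -13.0 for DNA replication (0.0105), -1.14 for mitochondrial complex I (0.768) and -5.35 for neddylation and cullin ligases (0.323). Over the first 4 of these together (163 genes), a union chosen after the data were examined, 45.7% of 455 guides were kept (41.2% to 50.3%), a shift of -5.33 points (permutation p = 0.0119). Its adjusted p of 0.0238 covers only this union and the olfactory group in both libraries, not 27 lists. Neither value accounts for the choice of the union. The shift was -3.67 points with DNA replication left out (permutation p = 0.116) and -4.53 points with complex I and neddylation added (permutation p = 0.00988). In B the shift was -1.04 points (permutation p = 0.418), and the difference between A and B was not tested. DNA replication genes, with 34.9% of guides kept in A (25.6% to 45.7%), had a permutation p of 0.0105, adjusted to 0.142 over 27 lists. Guides against olfactory, taste and hair keratin-associated genes were kept more often in A, by 4.60 points (adjusted permutation p = 0.0103), and not in B, at -0.544 points, a difference not tested.

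POU5F1, whose product maintains pluripotency, had 2 A guides with log2 ratios of 6.76 and 3.98 and 0 of 3 guides present in B. Chance among all genes may account for its place in A, since 6 genes reached its p of 0.000335 where 6.15 are given by chance. Whether an effect in all 3 B guides as large as the smaller one in A was missed because few cells were recovered was not decided. The chance that all 3 would be absent was 0.683 with no effect and 0.00114 with that effect, but the latter assumes recovery in proportion to abundance, and the gene was picked with its B guides known to be absent.

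Non-targeting guides with the same name in both libraries numbered 845 after the filter. Of these 60 were kept in both, where 51.7 are given by chance (Fisher's exact test p = 0.0560), and their kept shares adjusted for pool reads correlated at 0.0372 across guides (permutation p = 0.278).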
